A study of Mus musculus with 18 samples.

How the data were processed

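Expression was measured by sequencing messenger RNA of mouse hearts after myocardial infarction, in 6 groups of 3 libraries. The deposited tables hold 1 column per library in FPKM (fragments scaled by transcript length and by the mapped fragments of the library), computed by the authors, and no scaling between libraries was seen. No header names the unit. It was read from the values: length-weighted sums varied by 1.38% between the 18 libraries (coefficient of variation) and plain sums by 3.81%, as FPKM requires and TPM does not. The submitters' notes name HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8 and the genome build GRCm38.p6, without the role of each tool, the annotation or any filter. Each table holds 18414 genes, of which 18292 were matched to a RefSeq gene table for positions.

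Counts and total reads are not in the tables, so depth is unknown and no counting interval is given. A relative depth read from the smallest values was between 0.933 and 1.08. That reading keeps only values close to the smallest positive value of each gene, so it cannot show larger differences in depth. The 10 highest genes held between 8.82% and 14.8% of the FPKM of a library.

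Groups follow the sample titles. Each comparison used its 2 groups of 3 libraries, and genes with at least 1 FPKM in at least 3 of the 6 libraries were tested on log2(FPKM + 0.5). The test was limma 3.58.1 in R 4.3.3, with a trended and robust empirical Bayes fit and no pairing of replicate numbers. Changes are called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p values of genes are from limma and are two-sided. A two-sided exact permutation test of 3 against 3 cannot go below 0.1, so none was run gene by gene. The labels do not state that replicates are separate animals, and p values measure the spread between these samples. Differences between days were tested as contrasts in 1 fit of the 6 groups. On simulated data with the same spread, 2-fold changes were recovered in 83%, 55% and 46% of genes and 4-fold changes in 97%, 89% and 82% on days 3, 7 and 14. In these data 6, 12 and 12 unchanged genes were called. Genes were simulated as independent, so shifts shared by many genes of a library are not covered. Each simulation planted 100 changed genes of each size, which eases the adjusted threshold, so the recovered shares may not hold where few genes pass. On day 14, 20 genes induced by interferon gamma, gathered after the data were seen, had a median log2 fold change of 2.17 and 0 passed. Few or no calls therefore do not show that large changes were absent.

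Of 37 gene lists, 35 had at least 4 tested members on day 3. They were tested with camera (limma) at a preset correlation of 0.01 between genes, with adjustment over the lists. Adjusted p values of camera with an estimated correlation are given beside these calls, and those of fry for each list fixed beforehand that fry called. The lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined, and 6 further lists were added afterwards. Their p values were adjusted over those 6 lists alone, so they are not on the same footing as those of the lists fixed beforehand. Named genes are the 8 largest rises and 8 largest falls among called genes with non-overlapping groups and a mean of at least 1 FPKM, members of lists with the smallest p, and fixed anchor genes. Where no gene passed, the 5 genes with the smallest p were named.

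The alternatives were other scalings, filters and pseudocounts, a replicate block, 1 fit of all 18 libraries, a 2-fold threshold, other list tests and leaving out each library in turn. An atrial score as covariate, and leaving out libraries with at least 50 FPKM of the atrial gene Myl7, were added after the data were seen. For differences between days, camera with an estimated correlation was not planned either. Alternatives that need counts were not run. Results of some individual genes are not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.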

Results

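Messenger RNA was measured in hearts of mice after myocardial infarction, in 18 libraries that fall into 6 groups of 3. The injections were PBS (buffer) or 1 of 3 nanomedicines, aNMP-2a, aNMP-2b and aNMP-2c, whose names in the deposited tables refer to the M2a, M2b and M2c states of macrophages. Hearts were taken 1 day after the last injection. PBS_D3 and aNMP-2a_D3 mice received PBS or aNMP-2a on day 3, and tissue was taken on day 4. Mice of aNMP-2a+PBS_D7 and aNMP-2a+2b_D7 received aNMP-2a on day 3 and then PBS or aNMP-2b on day 7, with tissue on day 8. Mice of aNMP-2a+2b+PBS_D14 and aNMP-2a+2b+2c_D14 received both earlier agents and then PBS or aNMP-2c on day 14, with tissue on day 15. The FPKM values of a library summed to between 704356 and 814452, and between 12181 and 12821 genes reached 1 FPKM. Counts and read depths are not in the tables, so the depth behind each value is unknown. Across genes, libraries of the same group had Pearson r between 0.937 (aNMP-2a+2b+2c_D14) and 0.992 (PBS_D3). The Y-linked gene Ddx3y was at 0.02 FPKM or less in every library.

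Genes of neighbouring tissues were unequal between replicates. Myl7, an atrial myosin light chain, reached 1312 and 2982 FPKM in aNMP-2a_D3 replicates 1 and 3 and stayed at 1.28 FPKM or less in PBS_D3. It was also at 1350 FPKM in aNMP-2a+PBS_D7 replicate 2, at 2097 and 382 FPKM in aNMP-2a+2b_D7 replicates 1 and 2, at 85.1 and 930 FPKM in aNMP-2a+2b+PBS_D14 replicates 2 and 3 and at 770 FPKM in aNMP-2a+2b+2c_D14 replicate 2. Upk3b and Adipoq, genes of the outer lining of the heart and of fat, likewise differed between replicates on day 15. In aNMP-2a+2b+2c_D14, Adipoq was at 79.7 FPKM in replicate 1 and at 5.08 and 0.75 FPKM in replicates 2 and 3.

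The day 3 comparison asked how aNMP-2a changed the heart 1 day after injection, against PBS. Genes of the circadian clock shifted, with Arntl and Npas2 lower and Per1, Dbp and Hlf higher. Mesothelial genes such as Upk3b, Msln and Gpm6a rose, and the smooth muscle actin gene Acta2, the matrix protease Mmp3 and 6 cell cycle genes fell. The M2a-type and M2b-type macrophage lists were not called, while the M2c-type list was higher with the preset correlation but not with an estimated one (adjusted p = 0.455). Of 12512 genes tested, 176 rose and 54 fell, and 73 and 9 of these changed at least 2-fold. The 2 groups did not overlap for 22.9% of genes, against 10% by chance.

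The largest rises among the named genes were in Cyp2e1, a drug-metabolising enzyme (log2 fold change 3.47, adjusted p = 0.0291), and Upk3b (3.18, adjusted p = 0.0226). Cyp2e1 went from 0.13 ± 0.19 to 7.21 ± 3.96 FPKM, so the size of its log2 value depends on the 0.5 added to FPKM. Upk3b lies on chromosome 5 of GRCm38.p6 (136038496 to 136044993) and went from 2.00 ± 1.41 to 20.3 ± 3.66 FPKM (mean ± SD, n = 3). Angptl7, a secreted angiopoietin-like protein, rose by 2.83 on the log2 scale, from 1.31 ± 0.16 to 12.5 ± 2.39 FPKM (adjusted p = 2.92e-04). Msln (mesothelin, 2.81), Nkain4 (a sodium pump partner, 2.78), Lgals7 (galectin-7, 2.56), Chad (the matrix protein chondroadherin, 2.49) and Chil1 (a chitinase-like protein, 2.37) also rose. Chad was likewise low in PBS_D3 (0.05 to 2.85 FPKM). The largest fall was in Arntl, which encodes the clock factor BMAL1 (chromosome 7, 113178471 to 113314126). Arntl went from 9.99 ± 0.84 to 1.59 ± 0.42 FPKM (log2 fold change −2.34, adjusted p = 5.82e-04). The matrix proteases Adamts4 (−1.57) and Mmp3 (−1.39, from 35.0 to 13.0 FPKM, adjusted p = 8.23e-04) fell. So did the clock factor Npas2 (−1.24), the collagen chain Col5a3 (−1.13), the small GTPase Rasl11a (−1.12) and Leo1, a subunit of the transcription elongation complex PAF1 (−1.07). Acta2, on chromosome 19 (34240336 to 34255585), went from 254 ± 7.18 to 121 ± 9.74 FPKM (−1.07, adjusted p = 0.00104).

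**Figure D1:**
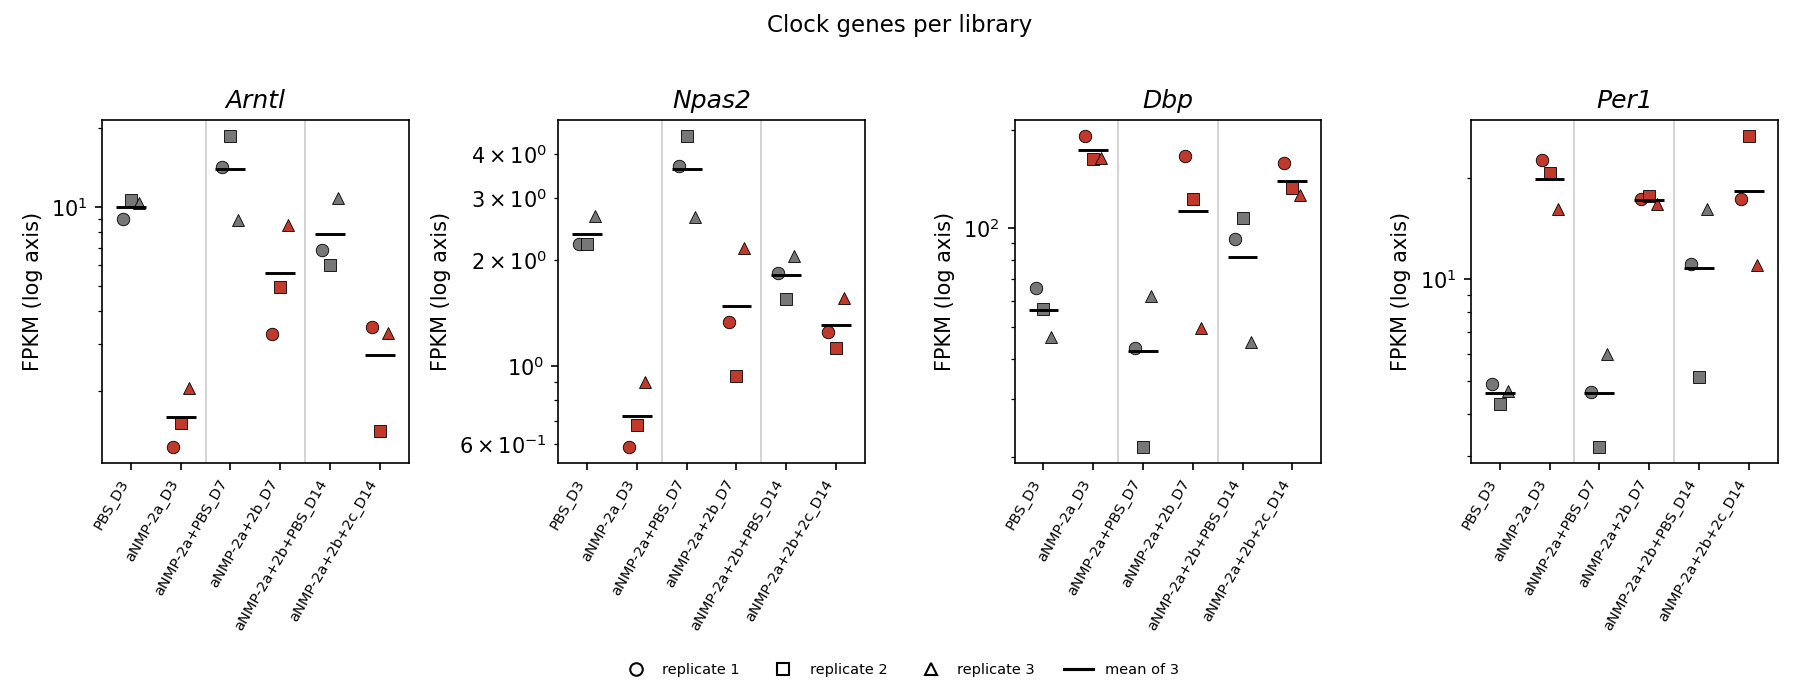
FPKM on a log axis of Arntl, Npas2, Dbp and Per1 in each of the 18 libraries, by group, with lines at the means of 3 libraries; red marks the groups whose last injection was a nanomedicine. Arntl went from a mean of 9.99 in PBS_D3 to 1.59 in aNMP-2a_D3, and Per1 from 4.61 to 19.8.

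The clock genes were gathered into lists after the data were seen. Of 11 genes that peak with Per, 9 rose, 0 fell and 2 did not pass, and 10 passed adjusted over the list alone. Per1 rose by 1.98 on the log2 scale, Hlf by 1.65, Dbp by 1.62 (56.2 to 173 FPKM) and Per3 by 1.86. The median of this list was 1.62, with adjusted p = 1.82e-15 from the preset correlation adjusted p = 0.0702 with an estimated correlation and 9.41e-04 by fry. Per2 (2.28) and Ciart (2.21) rose as well, while Nr1d1 had a log2 fold change of −0.05. Among 6 genes of the opposite phase, Arntl and Npas2 fell, Cry1 rose by 0.85 and Clock had a value of −0.37 (adjusted p = 0.15). Of 13 glucocorticoid-induced genes, also gathered afterwards, Tsc22d3 (1.34), Sult1a1 (0.85) and Klf9 (0.36) rose, 0 fell and 10 did not pass, and the list median was 0.13 (adjusted p = 0.16 by camera and 0.0139 by fry).

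The mesothelial list was higher (12 genes, median log2 fold change 1.67, adjusted p = 1.82e-09). Gpm6a (1.81), Lrrn4 (2.35), Upk3b, Msln and Krt18 (1.44) rose, 0 fell and 7 did not pass. Adjusted over the list alone, 9 rose. The call had adjusted p = 0.453 with an estimated correlation and 0.0442 by fry. Atrial genes went the same way without a gene passing (7 genes, median 1.89, adjusted p = 0.503 with an estimated correlation), and their call ended with the atrial covariate (0.23). That covariate is the mean of Myl7, Myl4, Sln, Mybphl and Bmp10, which are themselves in the atrial list, so this end was built in. Dkk3 had a log2 fold change of 1.89 and Tbx5 of 0.91. Red cell genes were higher, with Alas2 (1.07), Hbb-bs (0.85) and Hbb-bt (1.02) up, 9 of 12 not passing and 7 up adjusted over the list alone (adjusted p = 0.455 with an estimated correlation). The fibroblast list was not called (median 0.28, adjusted p = 0.303), and in it Dcn, the proteoglycan decorin, rose by 0.65. The adipocyte list had a median of −0.10 and a mean of 0.54, with adjusted p = 0.563.

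Of 28 cell cycle genes, 6 fell, 0 rose and 22 did not pass. Cdc20 fell by 0.89, Aurka by 0.77, Tpx2 by 0.73 and Kif20a by 0.71 on the log2 scale, and adjusted over the list alone 21 fell. The list median was −0.54, and the call had adjusted p = 0.455 with an estimated correlation. With the atrial score as a covariate the median was −0.21. With aNMP-2a_D3 replicates 1 and 3, rich in Myl7, left out it was −0.25, from 1 library against 3 of PBS_D3. All 14 mural genes (pericytes and smooth muscle) had negative values and Acta2 fell; Notch3 (−0.42) and Vtn (−0.49) passed adjusted over the list alone, 3 genes in all (adjusted p = 0.229 with an estimated correlation, 0.0442 by fry). The endothelial receptor Kdr fell by 0.69, from 73.4 to 45.1 FPKM (adjusted p = 0.0111), and the tight junction gene Cldn5 by 1.03. Both belong to the endothelial list (16 genes, 2 fell, 2 adjusted over the list alone), and Kdr also to the list of vessel growth factors and receptors (22 genes, 1 fell, 2 rose and 5 fell adjusted over the list alone). These lists were called lower, with adjusted p = 0.584 and 0.455 with an estimated correlation. The endothelial call ended with the replicate block and without PBS_D3 replicate 2 or aNMP-2a_D3 replicate 2 or 3. The other call ended with the atrial covariate and without PBS_D3 replicate 2 or aNMP-2a_D3 replicate 1.

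Among macrophage genes, the M2c-type list was higher (18 genes, median 0.22). Selenop (0.64) and the bridging ligand Gas6 (0.43) rose, 16 did not pass and 3 rose adjusted over the list alone (adjusted p = 0.455 with an estimated correlation). In the resident macrophage list Vsig4, a complement receptor, rose by 1.58 and Gas6 rose, 11 did not pass, and adjusted over the list alone 5 rose and 1, Cx3cr1 (−0.58), fell (adjusted p = 0.503 with an estimated correlation), and the call ended without aNMP-2a_D3 replicate 2. The M2a-type list had a median of −0.14 and no member passed (16 genes, adjusted p = 0.563), with Cd209a at 0.73 and Igf1 at 0.59. The M2b-type list had a median of −0.15 over 9 genes (adjusted p = 0.563), with Cd86 at 0.34 and Sphk1 at −0.49, and was called lower without PBS_D3 replicate 2 (−0.39). Complement genes were higher. C4b had a log2 fold change of 0.60 and C2 of 0.86, and 3 of 17 genes rose adjusted over the list alone (adjusted p = 0.503 with an estimated correlation). The lists of recruited macrophages (median 0.07), neutrophils (0.05), T and NK cells (0.05, mean 0.09, camera direction down), dendritic cells (−0.03), B cells (−0.17) and interferon response (0.29, adjusted p = 0.0952) were not called.

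In the extracellular matrix, Chad rose and Col12a1 fell by 0.94, and the list of 29 scar matrix genes was not called (median −0.19, mean 0.03, adjusted p = 0.0692). Of 20 proteases and inhibitors, the inhibitor Timp3 rose by 1.17 (61.6 to 139 FPKM, adjusted p = 5.82e-04), while Mmp3, Plau (−0.58) and Adamts4 fell. Col1a1 had a log2 fold change of −0.58 and Postn of 0.29, and neither passed. Among other lists that were not called, cardiomyocyte genes had a median of −0.07, myofibroblast genes of −0.10, fetal and wall stress genes of −0.21 (mean 0.07) and oxidative phosphorylation genes of −0.04. Antioxidant genes were at −0.07, lysosome genes at 0.15, classical inflammation genes at −0.27, immediate early genes at 0.17, nerve genes at 0.28 and genes of other thoracic tissues at 0.12. Myh7, a fetal myosin gene, rose by 1.43 (24.0 to 66.8 FPKM), and the NRF2 target Nqo1 fell by 0.70. Postn was at −0.35 without aNMP-2a_D3 replicate 3. Lists of the unfolded protein response (17 genes, median −0.22), glycolysis and hypoxia (19, −0.15) and fatty acid oxidation (25, −0.13) were lower. Herpud1 rose by 0.50, no member of these lists fell over all genes, and adjusted over the list alone 8, 5 and 0 fell. These calls had adjusted p = 0.229, 0.229 and 0.799 with an estimated correlation, and by fry the first 2 had adjusted p = 0.0442. The fatty acid oxidation call ended with the atrial covariate and without aNMP-2a_D3 replicate 3.

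Without PBS_D3 replicate 1, 2 or 3 the count of 230 genes became 82, 77 or 71. Fits with an atrial score as a covariate and of all 18 libraries gave 22 and 3 genes, and of the genes named here Angptl7, Nkain4, Gpm6a, Per1, Hlf, Tsc22d3, Timp3, Arntl, Mmp3 and Acta2 passed under every alternative except the fit of all 18 libraries, where Arntl and Leo1 passed.

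**Figure D2:**
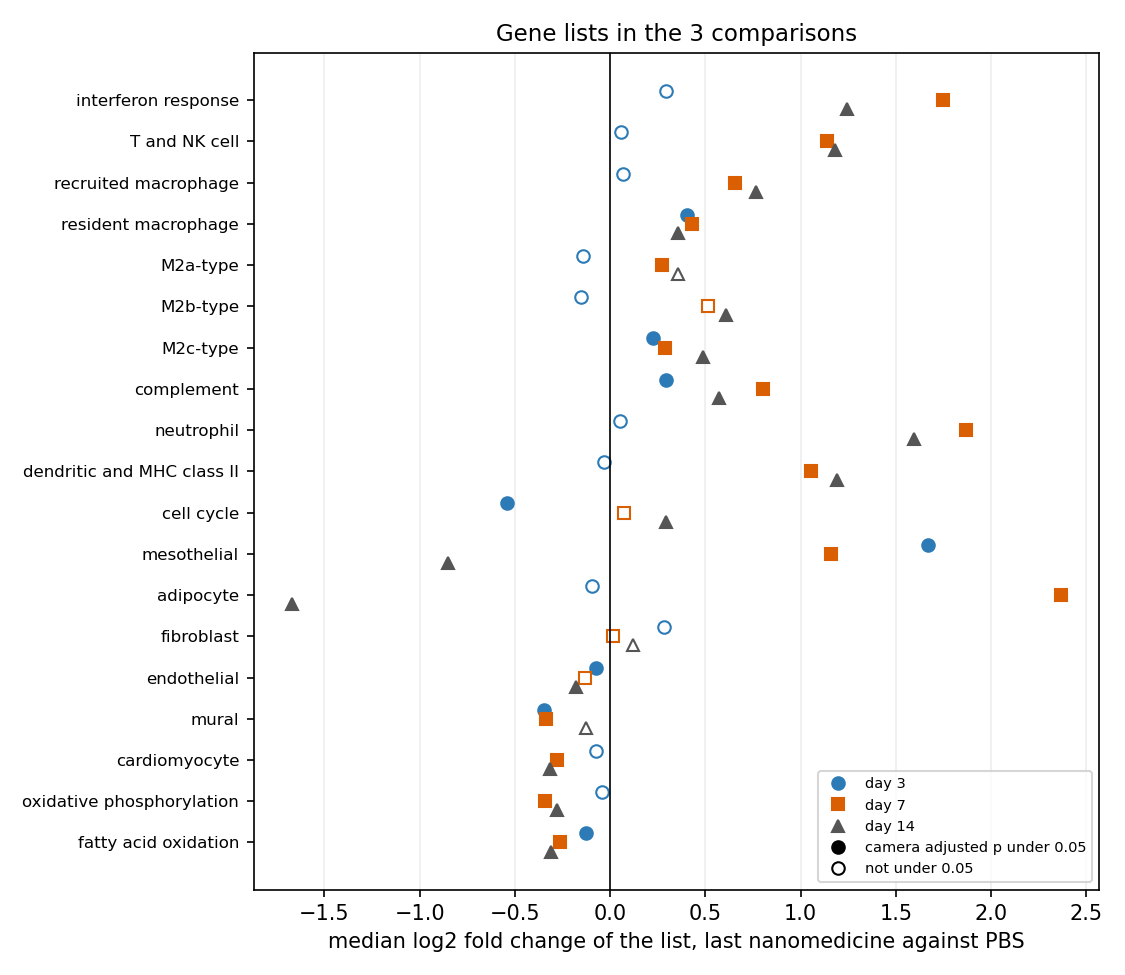
Median log2 fold change, last nanomedicine against PBS, of 19 gene lists in the day 3, day 7 and day 14 comparisons; filled symbols have an adjusted p under 0.05 by camera with the preset correlation. The interferon list was at 0.29, 1.75 and 1.24, and the adipocyte list at −0.10, 2.37 and −1.67.

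The day 7 comparison asked what aNMP-2b added on day 7 in mice that had received aNMP-2a. Granzyme A, the cytotoxic protease gene Gzma, rose and was the gene that passed. Values of every tested gene of the interferon response list were positive. With the preset correlation, lists of complement, fat and mesothelium were also called higher and those of oxidative phosphorylation and cardiomyocytes lower. No member of these lists passed over all genes, and none of these calls held with an estimated correlation, where adjusted p lay between 0.156 and 0.559. A list of MHC class I genes, gathered after the data were seen, was called higher too. No member of it passed over all genes. Its adjusted p with an estimated correlation was 0.0611, adjusted over the 6 added lists alone. Gzma (chromosome 13, 113093824 to 113100981) went from 5.51 ± 0.40 to 37.4 ± 7.03 FPKM (n = 3, log2 fold change 2.64, adjusted p = 0.0156). Of 12711 genes, 1 rose and 0 fell, 989 had an unadjusted p under 0.05, and the groups did not overlap for 12.3% (10% by chance).

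The interferon list had a median log2 fold change of 1.75 over 22 genes, all with positive values. No member passed over all genes, 21 rose adjusted over the list alone, and the call had adjusted p = 0.244 with an estimated correlation. Ifi27l2a was at 1.84 (389 to 1429 FPKM), the transcription factors Irf7 at 2.49 and Irf9 at 1.03, and Xaf1 at 2.01. Left out in turn, single libraries gave medians from 1.27 to 2.07. Of 17 T and NK cell genes, Gzma rose and 16 did not pass, and 6 rose adjusted over the list alone (median 1.14, adjusted p = 0.208 with an estimated correlation). Perforin (Prf1) was at 1.75, Gzmb at 2.56 and Nkg7 at 1.84. In lists gathered after the data were seen, all 17 genes of MHC class I processing were higher and rose adjusted over the list alone (median 1.28, adjusted p = 0.0611 with an estimated correlation, 0.00694 by fry). Genes induced by interferon gamma had a median of 2.42 and Gbp6 went from 20.2 to 302 FPKM (adjusted p = 0.121 with an estimated correlation).

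Complement genes were higher (17 genes, median 0.80). None passed over all genes, 10 rose adjusted over the list alone, and the call had adjusted p = 0.197 with an estimated correlation and 0.0452 by fry. C2 was at 1.67, Cfb at 2.05 (23.4 to 98.5 FPKM) and C4b at 1.56. The adipocyte list had a median of 2.37 over 10 genes, with Cfd at 2.89, Adipoq at 2.76 and Cidec at 2.63. No member passed over all genes, 8 rose adjusted over the list alone, and the call had adjusted p = 0.156 with an estimated correlation and 0.021 by fry. Mesothelial genes were again higher (12 of 12 positive, median 1.16), with C3 at 1.30 and Lrrn4 at 1.21, 3 up adjusted over the list alone and adjusted p = 0.197 with an estimated correlation. C3 is also in the complement list, so its value is not particular to mesothelium. Without aNMP-2a+PBS_D7 replicate 1 this median was 0.67.

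Among myeloid genes, recruited macrophage genes had a median of 0.65, with Ly6c2 at 2.01 and Plac8 at 2.15. Without aNMP-2a+PBS_D7 replicate 1, 2 or 3 it was 1.30, 0.31 or 0.42. Resident macrophage genes were at 0.43 (Timd4 1.11, Folr2 0.71), neutrophil genes at 1.87 (Elane 2.58, Mpo 2.18, 2 up adjusted over the list alone), MHC class II and dendritic genes at 1.05 (H2-DMb1 1.42) and B cell genes at 0.76 (Jchain 1.52, 1 up adjusted over the list alone). The M2c-type list had 18 of 18 positive values with a median of 0.29 (C1qb 0.93, C1qc 0.87) and the lysosome list was at 0.30 (Npc2 0.70). The M2a-type list was called higher (median 0.27, adjusted p = 0.0332, Clec10a 0.60 and Chil3 2.04) and the M2b-type list was not (0.51, adjusted p = 0.0642, Cd86 0.84). With an estimated correlation, adjusted p = 0.208 for the resident macrophage list, and for the other lists of this paragraph it lay between 0.534 and 0.66. The M2a-type call ended without aNMP-2a+PBS_D7 replicate 2 or 3 or aNMP-2a+2b_D7 replicate 3. The M2b-type list passed without aNMP-2a+PBS_D7 replicate 1, with upper-quartile scaling and with the atrial covariate.

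All 27 genes of oxidative phosphorylation had negative values (median −0.34), with Idh3a and Uqcrc1 both at −0.45. Cardiomyocyte genes were at −0.28 (Actc1 −0.77), fatty acid oxidation genes at −0.26 (Etfb −0.48) and mural genes at −0.34 (Acta2 −1.48), and genes of vessel growth factors were lower with Kdr at −0.73 (76.0 to 45.6 FPKM), Apln at −1.07 and Vegfa at −0.51. No member passed over all genes, and Kdr passed adjusted over the list alone. These 5 calls had adjusted p = 0.559, 0.559, 0.66, 0.208 and 0.197 with an estimated correlation, in the order given. The calls of oxidative phosphorylation, cardiomyocyte and fatty acid oxidation genes ended without aNMP-2a+2b_D7 replicate 2, where the medians were −0.12, −0.19 and 0.01, and the fatty acid oxidation call also without aNMP-2a+PBS_D7 replicate 2 or 3. The unfolded protein response list was higher (0.20, Ddit3 0.55, Chac1 1.08, 2 up adjusted over the list alone, adjusted p = 0.559 with an estimated correlation), and its call ended without aNMP-2a+2b_D7 replicate 3 (0.06). Fibroblast (0.01), endothelial (−0.13) and atrial (0.82) lists were not called, and the atrial list had Myl7 at 1.83. The Per-phase clock list had 11 of 11 positive values and a median of 1.00 (adjusted p = 8.23e-10 with the preset correlation, 0.121 with an estimated correlation and 0.0572 by fry). In it 6 rose adjusted over the list alone and Per1 was at 1.83 (adjusted p = 0.0922), and Arntl was at −1.28. Glucocorticoid-induced genes had a median of 0.60 (5 of 13 up adjusted over the list alone, adjusted p = 0.143 with an estimated correlation).

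Without aNMP-2a+PBS_D7 replicate 1 the day 7 count was 277 genes, and without aNMP-2a+PBS_D7 replicate 2 or 3 or aNMP-2a+2b_D7 replicate 2 or 3 it was 0. With the replicate number as a block Gzma had adjusted p = 0.145 and the count was 0. A fit of all 18 libraries gave 17 genes, among them Gzma, Prf1, Irf7, Irf9 and Xaf1 up and Kdr down.

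**Figure D3:**
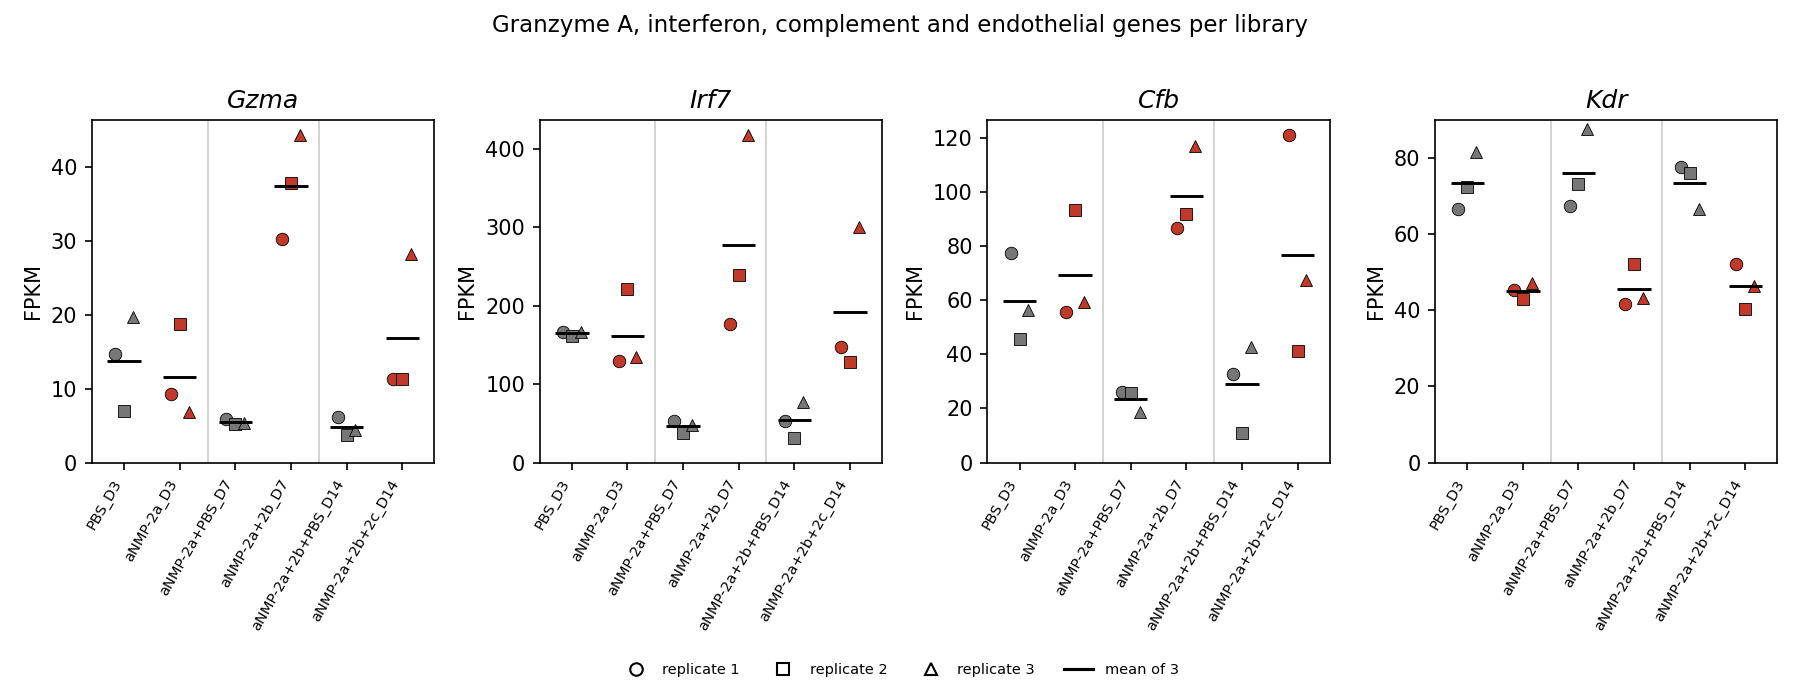
FPKM of Gzma, Irf7, Cfb and Kdr in each of the 18 libraries, by group, with lines at the means of 3 libraries; red marks the groups whose last injection was a nanomedicine. Gzma went from a mean of 5.51 in aNMP-2a+PBS_D7 to 37.4 in aNMP-2a+2b_D7, and Kdr was lower in the nanomedicine group of each pair.

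The day 14 comparison asked what aNMP-2c added on day 14 in mice that had received both earlier agents. No gene passed, and values of every interferon gene tested were again positive. With the preset correlation, lists of interferon, T cell, MHC class II and classical inflammation genes were called higher and lists of cardiomyocyte, mitochondrial and endothelial genes lower. None of these calls held with an estimated correlation (adjusted p = 0.685), and the lower ones ended without aNMP-2a+2b+2c_D14 replicate 1. Of 12440 genes, 0 rose and 0 fell by limma, 1064 had an unadjusted p under 0.05, and the groups did not overlap for 15.4% (10% by chance). The 5 genes with the smallest unadjusted p shared adjusted p = 0.381. Cabp1, a calcium-binding protein gene, had a log2 fold change of −1.37 and the kinase gene Alpk2 of −0.85. Sp110, a nuclear body protein gene, was at 1.11, Uba7, the activating enzyme of the ubiquitin-like protein ISG15, at 1.27 (24.1 to 60.1 FPKM), and Gm4951 at 2.13.

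The interferon list had a median of 1.24 with 22 of 22 values positive, and 19 rose adjusted over the list alone (adjusted p = 0.685 with an estimated correlation). Zbp1 was at 2.40 (14.3 to 74.8 FPKM) and Ifit3 at 2.14. Left out in turn, single libraries gave medians from 1.05 to 1.52. T and NK cell genes had a median of 1.18, with Cd2 at 1.10, Cd3g at 1.68, Cd3e at 1.54 and Gzma at 1.61, and 12 of 15 rose adjusted over the list alone. Genes of MHC class II and dendritic cells were at 1.19 (H2-DMa 1.74, Ciita 1.58, 8 up adjusted over the list alone). Classical inflammation genes were at 0.83 (Cxcl10 2.37, Cxcl9 2.55, 4 up adjusted over the list alone). All of these calls had adjusted p = 0.685 with an estimated correlation. Gathered after the data were seen, 20 of 20 interferon gamma genes were higher (median 2.17; Igtp 64.6 to 644 FPKM), as were 17 of 17 genes of MHC class I processing (median 1.09; Tap1 1.96), and both had adjusted p = 0.12 with an estimated correlation and 0.0466 by fry.

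Recruited macrophage genes had a median of 0.76 (Plac8 2.23, Cd68 1.08), neutrophil genes of 1.60 (Hdc 1.33, Lcn2 2.36), complement genes of 0.57 (C6 0.72, Serping1 0.84), lysosome genes of 0.21 (Timd4 1.30) and M2c-type genes of 0.49 (Selenop 0.40, Axl 0.47). All of these calls ended without aNMP-2a+2b+2c_D14 replicate 1, with medians of 0.50, 0.72, 0.18, 0.05 and 0.27. The resident macrophage list was at 0.36, the M2b-type list at 0.61 (adjusted p = 0.0244, Cd86 0.70, Cd40 0.58, 2 up adjusted over the list alone) and the cell cycle list at 0.29 (Mcm6 0.53, Mcm3 0.58). The M2a-type list was not called (0.36, adjusted p = 0.0947, Socs1 1.64). It was called higher with the replicate block and with upper-quartile scaling. Of the fits that left out a library in turn, 3 called it higher and 3 did not. With an estimated correlation adjusted p = 0.884 for the cell cycle list and 0.685 for the others. Leaving out aNMP-2a+2b+2c_D14 replicate 1 ended the M2b-type, resident macrophage and cell cycle calls too (0.39, 0.10 and 0.04).

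Genes of fatty acid oxidation (median −0.31, Pdk4 −1.52), oxidative phosphorylation (−0.28, Uqcrc1 −0.43), cardiomyocytes (−0.32, Myh6 −0.74, 4879 to 2909 FPKM) and endothelium (−0.18, Kdr −0.66, Tie1 −0.43) were lower as lists. No member passed over all genes, and Kdr passed adjusted over the list alone. Without aNMP-2a+2b+2c_D14 replicate 1 these calls ended, with medians of −0.11, −0.06, −0.07 and −0.12. The adipocyte list was at −1.67 (Cidea −0.35; Cfd 357 to 211 FPKM) and the mesothelial list at −0.85 (Upk3b −2.88, Msln −2.37). Their medians were −0.64 and −0.33 without aNMP-2a+2b+2c_D14 replicate 3, and the mesothelial call ended without replicate 2 or 3. All 6 lists had adjusted p = 0.685 with an estimated correlation. Fibroblast (0.12), mural (−0.13) and atrial (−0.16) lists were not called. The Per-phase clock list had 10 of 11 positive values and a median of 0.55 (adjusted p = 2.27e-04 with the preset correlation, 0.12 with an estimated correlation and 0.0466 by fry). Arntl was at −1.41 and Dbp at 0.85, and neither passed over all genes.

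**Figure D4:**
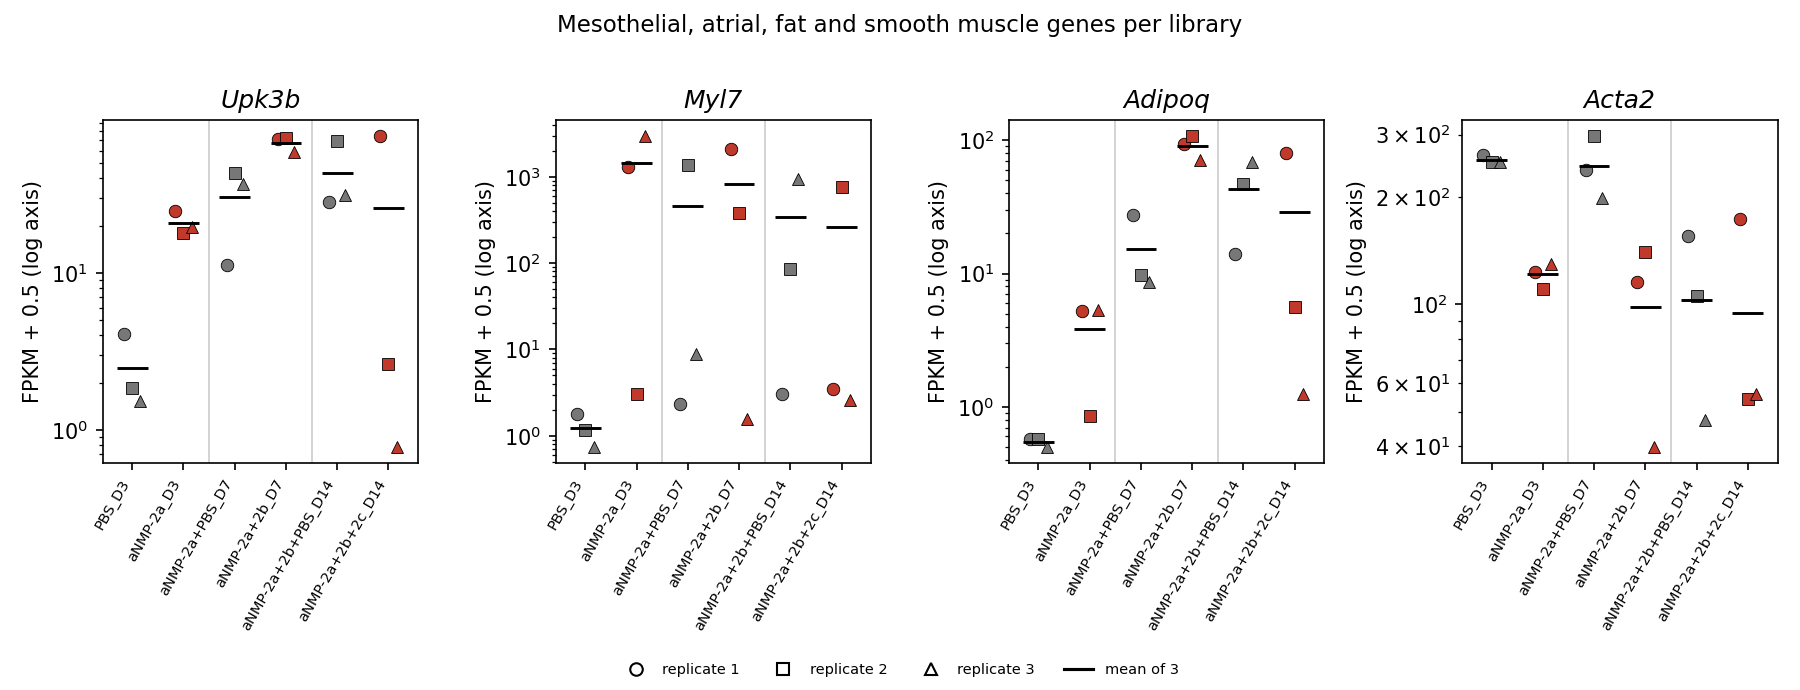
FPKM plus 0.5 on a log axis of Upk3b, Myl7, Adipoq and Acta2 in each of the 18 libraries, by group, with lines at the means of 3 libraries; red marks the groups whose last injection was a nanomedicine. Myl7 ran from 0.24 FPKM in PBS_D3 replicate 3 to 2982 FPKM in aNMP-2a_D3 replicate 3.

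Anchor genes were fixed for all comparisons. The fetal gene Nppb was at −0.31, 0.32 and −0.22 on days 3, 7 and 14, the macrophage genes Mrc1 at 0.18, 0.10 and 0.36, Cd163 at 0.40, 0.29 and 0.02 and Arg1 at −0.22, −0.94 and 0.56. Il1b was at −1.28, −0.37 and 0.64, S100a8 at 0.08, 2.40 and 2.81, Vegfa at −0.26, −0.51 and −0.50, Col1a1 at −0.58, 0.12 and −0.08 and Postn at 0.29, 0.22 and 0.32. None of them passed in any of the 3 comparisons. Mean FPKM of Col1a1 went against the sign of its log2 value on day 7 (573 to 459) and day 14 (157 to 356), so its direction there depends on the scale. Il10, tested on days 7 and 14, was at 0.72 and 0.87. Without aNMP-2a+PBS_D7 replicate 1, Arg1 was at 0.27 and Il1b at 1.12 on day 7, and without aNMP-2a+2b+2c_D14 replicate 1 Postn was at −0.79 on day 14.

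Time courses under the same nanomedicine were also compared. From day 4 to day 8 tissue, aNMP-2a+PBS_D7 against aNMP-2a_D3, the plasma cell gene Mzb1 rose (2.24). The clock genes Ciart (−2.67) and Per2 (−2.66) and the interferon genes Ifi27l2a (−1.82, 1385 to 389 FPKM) and Oas1g (−1.45) fell, and these 5 of 12585 genes passed. All 22 interferon genes had negative values (median −1.55), 1 fell over all genes and 22 fell adjusted over the list alone. Complement (−0.66), resident macrophage (−0.69, Cbr2 −1.40), M2c-type (−0.53) and recruited macrophage (−0.54) lists were lower, and B cell genes (1.63, Jchain 3.21), adipocyte (1.84), mural (0.28) and endothelial genes (0.21, Cldn5 1.51, Kdr 0.74) were higher. With an estimated correlation the smallest adjusted p among the lists fixed beforehand was 0.179. The count was 454 genes without aNMP-2a+PBS_D7 replicate 1 and 0 without aNMP-2a_D3 replicate 2 or 3 or aNMP-2a+PBS_D7 replicate 2. With the replicate block it was 0 as well, and 11 genes passed in another split of the same 6 libraries. These groups share the aNMP-2a_D3 libraries with the day 3 comparison and the aNMP-2a+PBS_D7 libraries with the day 7 comparison.

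From day 8 to day 15, aNMP-2a+2b+PBS_D14 against aNMP-2a+2b_D7, the neutrophil elastase gene Elane (−2.90) and Gzma (−2.85, 37.4 to 4.79 FPKM) fell, and no other of 12607 genes passed. Lower lists included interferon (−1.44, Irf7 −2.36, 18 down adjusted over the list alone), T and NK cell (−1.26, 13 down adjusted over the list alone), recruited macrophage (−1.29, Cd68 −1.36), B cell (−1.78, Jchain −1.85) and scar matrix genes (−1.26, Ecm1 −0.94, Tnc −2.46). Oxidative phosphorylation genes were higher in 27 of 27 cases (0.58, 25 up adjusted over the list alone), with fatty acid oxidation (0.58) and cardiomyocyte genes (0.52, Actn2 0.52). All of these had adjusted p between 0.472 and 0.478 with an estimated correlation. Mesothelial genes were lower in 12 of 12 cases (−0.76, adjusted p = 0.472 with an estimated correlation and 0.0475 by fry). The count was 0 when any aNMP-2a+2b_D7 library, or aNMP-2a+2b+PBS_D14 replicate 2 or 3, was left out, and 0 with the replicate block. These groups share the aNMP-2a+2b_D7 libraries with the day 7 comparison and the aNMP-2a+2b+PBS_D14 libraries with the day 14 comparison, so falls of genes that rose on day 7, such as Gzma, are not independent of it. The later group of each time course also had a further PBS injection and more time since its last nanomedicine. These, day of tissue and any batch of tissue or library preparation cannot be told apart.

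The responses to the last nanomedicine were then compared between days in 1 fit of all 18 libraries. No gene differed by limma between days 7 and 3, 14 and 7, or 14 and 3, and 629, 345 and 642 of 13116 genes had an unadjusted p under 0.05. Each of these counts is below the share of 0.05 that chance alone would give. Without aNMP-2a+2b+2c_D14 replicate 1 the counts for days 14 and 7 and for days 14 and 3 were 77 and 82. With the preset correlation 18, 5 and 15 lists differed, with a median difference of 1.43 over interferon genes between days 7 and 3 (adjusted p = 0.572 with an estimated correlation). Over cell cycle genes the median difference between days 14 and 3 was 0.79 (adjusted p = 0.471 with an estimated correlation). In the adipocyte list the difference between the responses of days 14 and 7, taken gene by gene, had a median of −4.21 (adjusted p = 0.0292 with an estimated correlation). The estimated correlation was not planned for these contrasts. The agents differ between days, so agent and day cannot be told apart.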

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

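The value here comes from a planned test, and the values per library were looked up after its result was seen. The response of the adipocyte list differed between days: the log2 change on day 14 minus that on day 7, taken gene by gene in the fit of all 18 libraries, had a median of −4.21 (adjusted p = 0.0292 by camera with an estimated correlation). Adipoq was at 26.8, 9.33 and 8.15 FPKM in aNMP-2a+PBS_D7 and at 93.6, 108 and 70.7 FPKM in aNMP-2a+2b_D7. On day 15 it was at 13.5, 46.4 and 68.1 FPKM in aNMP-2a+2b+PBS_D14 and at 79.7, 5.08 and 0.75 FPKM in aNMP-2a+2b+2c_D14. No explanation, technical or biological, was tested.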

How the results depend on the processing

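The atrial settings were chosen after the data were seen. The estimated correlation was not planned for differences between days, and the other settings were planned. On day 3 the 230 genes became 82 with at least a 2-fold change, 3 in 1 fit of all 18 libraries, 22 with the atrial score as covariate, and 71 to 237 leaving out 1 library. Of 49 named called genes, 1 kept its call under every setting run. The day 7 count of 1 became 4 with the stricter filter, 17 in the fit of all 18 libraries, 0 with the replicate block, 0 with atrial-bearing libraries left out, and 0 to 277 leaving out 1 library. The day 14 count was 0 by limma under all settings run, with 1064 genes at an unadjusted p under 0.05. The time courses gave 0 genes with the replicate block and 0 with no filter on low values, and leaving out 1 library 0 to 454 (days 4 to 8) and 0 to 2 (days 8 to 15). For lists, an estimated correlation gave 0 calls on each day, and fry gave 4, 2 and 0 on days 3, 7 and 14. Leaving out 1 library, the day 14 lists ran from 9 (without aNMP-2a+2b+2c_D14 replicate 1) to 20. Differences between days ran from 0 to 77 genes (day 14 minus day 7) and from 0 to 82 (day 14 minus day 3), both highest without that same library. Leaving out atrial-bearing libraries left 1 library after the last nanomedicine against 3 on day 3 and 1 against 2 on day 7, and on day 14 1 PBS library against 2, so the single library was assumed to vary like the other group. In these fits day 7 values of Col1a1, Postn and Mzb1 reversed to −0.88, −1.37 and −0.11, the day 7 fatty_acid_oxidation list to 0.23 and the day 14 epicardial_mesothelial list to 0.19. Leaving out 1 library, values ran from −0.35 to 0.68 for Postn on day 3, and on day 7 from −0.29 to 0.76 for Nppb and −1.39 to 1.12 for Il1b. They ran from −1.65 to 0.27 for Arg1, day 7 comparison, −0.54 to 0.014 for the fatty_acid_oxidation list and 0.057 to 0.34 for the unfolded_protein_response list, whose test direction reversed at the lowest value. On day 14 they ran from −0.79 to 0.95 for Postn and −0.16 to 1.16 for Il1b. Fewer samples enter the fits with libraries left out, and the cause of the other changes was not tested. Scaling moved the median of all genes by less than 0.1. DESeq2-type and other count-based alternatives were not run because the tables hold no counts, and unknown depth limits what can be said of genes near 1 FPKM.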

Other observations

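All tests of this part, the average over the 3 comparisons included, were chosen after the results were seen. Kdr, the main endothelial receptor for VEGF, was lower after each of the 3 nanomedicines. It ran from 40.4 to 52.2 FPKM in the 9 libraries whose last injection was a nanomedicine and from 66.4 to 87.5 FPKM in the 9 whose last was PBS. In 1 fit of all 18 libraries the average of the 3 responses was −0.69 on the log2 scale for Kdr (limma adjusted p = 0.00137), −0.75 for Leo1, −1.68 for Arntl, 0.51 for the protease gene Ctso and 1.63 for the glycolytic regulator Pfkfb3. By this average 415 genes rose and 164 fell, 579 in all. Of 100 groupings of the libraries 1, the real one, gave as many, and the highest of the others gave 19. The count was 151 without aNMP-2a_D3 replicate 2 and 1373 without aNMP-2a+PBS_D7 replicate 1. Cd86 (0.63), C1qb (0.75) and Ifit3 (1.79) also rose on average, and so did Irf7 (1.41), which had −0.07 on day 3. The clock genes Per1 (1.53) and Npas2 (−0.89) changed on average too, so time of collection stays open for the average as well. The interferon list had an average of 1.11, with adjusted p = 0.263 with an estimated correlation.

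Among 12231 genes, 39 were higher and 29 lower without overlap in all 3 comparisons, where independent comparisons would give 11.4 and 3.08. Of 4000 relabellings 14 gave at least 68, and the highest other gave 176. Across genes, which are not independent replicates, fold changes of days 7 and 14 had Pearson r = 0.66 and Spearman rho = 0.54, and 4 of 200 relabellings gave an r as large (highest other 0.753). For days 3 and 7 r was 0.33 and rho 0.34, with 22 of 200 as large, and for days 3 and 14 they were 0.11 and 0.29, with 69 of 200, so chance cannot be excluded for these pairs. The 4 of 200 for days 7 and 14 include the real grouping. They belong to the highest of the 3 pairs, without adjustment for that choice, so chance is not firmly excluded there either.

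The shift of clock genes was weighed on day 3, where it may reflect tissue taken at another time of day. Per-phase genes lay 1.99 above Arntl-phase genes on the log2 scale, but time of collection is not in the labels, and it and a response of the clock to aNMP-2a cannot be told apart. On day 3 the Per-phase median lay 1.497 above that of glucocorticoid targets, whose SD across genes was 0.71. This argues against induction by glucocorticoid as the whole cause only if that would raise both lists alike. The targets were also higher by fry (adjusted p = 0.0139), so induction by glucocorticoid is not excluded on day 3. On day 7 the medians were 1.00 for Per-phase genes and 0.60 for glucocorticoid targets, of which 11 of 13 were positive (adjusted p = 6.33e-05 with the preset correlation and 0.143 with an estimated correlation), so for day 7 and for the average this explanation was not tested and stays open.

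Mesothelial genes were higher on day 3 in 11 of 12 cases. With the atrial score as a covariate their median was 1.70. That value rests mainly on aNMP-2a_D3 replicate 2, whose score (0.34) was near those of PBS_D3 (−0.32 to −0.06). The scores of replicates 1 and 3 were 7.82 and 7.59. It therefore argues only weakly, through a single library, against atrial tissue as the whole cause. A lower share of muscle cells would raise other cell types alike, yet the mesothelial median lay 1.39 above that of fibroblast genes (SD across genes 0.39). With 1 library left out in turn, this difference ran from 1.25 to 1.69. More of the outer surface of the heart in the treated pieces and a response of surface cells to aNMP-2a cannot be told apart, since both raise these genes together.

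Interferon genes lay 1.74 on day 7 and 1.13 on day 14 above fibroblast genes (SD 0.28 and 0.31). Each SD here is over the genes of the reference list and does not measure the spread between libraries. With 1 library left out in turn, interferon genes lay 1.10 to 2.11 on day 7 and 0.726 to 1.52 on day 14 above the highest of the fibroblast, endothelial and mural medians. This argues against a lower share of muscle cells as the whole cause. Interferon genes lay above recruited macrophage markers by 1.10 on day 7 (SD 0.77) and by 0.48 on day 14 (SD 0.59). The day 7 difference from these markers was 0.50 without aNMP-2a+PBS_D7 replicate 1 (SD 0.73) and 0.43 without aNMP-2a+2b_D7 replicate 3 (SD 0.72), within their spread. More recruited macrophages with unchanged expression and a higher response per cell cannot be told apart on either day. A response to aNMP-2b or aNMP-2c remains a hypothesis.

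Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. On day 3 the real split gave 230 genes and the highest other 0, with 1 of 10 as large. On day 7 these were 1 and 0 (1 of 10), on day 14 0 and 0 (10 of 10, fixed by a real count of 0), from day 4 to 8 they were 5 and 11 (2 of 10) and from day 8 to 15 they were 2 and 0 (1 of 10). Lists called were 13 against 21 on day 3 (4 of 10), 19 against 22 on day 7 (3 of 10) and 18 against 25 on day 14 (4 of 10). For differences between days the real count was 0, so 100 of 100 groupings gave as many in each contrast whatever the data, and this says nothing about chance. The highest others were 21 (day 7 minus day 3), 1854 (day 14 minus day 7) and 61 (day 14 minus day 3), and with 1854 genes against 0 the grouping points to a structure of the samples. It placed aNMP-2a+PBS_D7 replicate 1 with aNMP-2a+2b_D7 replicates 1 and 2, and aNMP-2a+2b+2c_D14 replicate 2 with aNMP-2a+2b+PBS_D14 replicates 2 and 3. On day 14 the libraries placed together are those with Myl7 above the cut (85.1, 930 and 770 FPKM, against 2.53, 2.97 and 2.07 in the others). On day 7 they are those with higher medians of genes of other thoracic tissues (2.99, 2.88 and 2.88 in log2(FPKM + 0.5), against 1.01, 0.99 and 0.89). Medians of cell cycle genes, on the same scale, separated the same libraries on both days, in opposite directions. On day 7 the libraries placed together were higher (2.61, 2.16 and 2.49, against 1.58, 1.77 and 1.57). On day 14 they were lower (1.201, 0.948 and 0.899, against 1.808, 2.12 and 1.622). Recruited macrophage medians were also lower in them on day 14 but overlapped on day 7. On day 7 the libraries placed together also had more genes with at least 1 FPKM (12770, 12775 and 12772, against 12474, 12329 and 12437). On day 14 these numbers overlapped. The levels and gene numbers were looked up after the grouping was seen, and whether they account for the 1854 genes was not tested.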
